A study of Homo sapiens with 2 samples.

How the data were processed

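Total RNA of the 2 K562 cultures was extracted with a column kit, biotin-labelled by an Affymetrix whole-transcript sense target protocol and hybridised to 1 Affymetrix array per culture, per the labels' protocols. The series' design text names the HG-U133 Plus array, whereas the probe set numbers, the number of probe sets and the platform annotation are those of a whole-transcript Gene ST array, and the latter were used here. The deposited log2 values were made by the authors with Affymetrix Expression Console 1.1.1 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes probes over the arrays processed together and summarises each probe set by median polish. It shrinks differences of dim probe sets and would remove a shift shared by all genes. That the scale is log2 was taken from RMA and from the range of the values, 1.61 to 14.6, because no label states the base. The arrays normalized together are not given in the sources used here; the 2 columns were close to equal in distribution but not identical after sorting, with quartiles of 5.12, 6.77 and 8.54 in the doxycycline sample and 5.12, 6.78 and 8.52 in the control sample.

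The table held 33297 probe sets and 0 missing values. By the platform annotation, 19460 probe sets had 1 gene symbol, 1754 had several and 12083 had none here. Symbols were updated through their Entrez IDs to NCBI RefSeq on GRCh38.p14, where 19429 of the 19460 matched. This table was used for names and for the genomic span of genes only. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols were kept out of the gene comparison. The probe set shared by BMI1 and COMMD3-BMI1 is one of them and is reported on its own, since BMI1 had no other. A gene took the value of its probe set with the highest mean over both samples, which gave 18417 genes, 769 of them with at least 2 probe sets. Genes whose higher log2 value was under 6 were left out, which kept 13471 genes. In the doxycycline sample 20768 probe sets reached 6, and in the control sample 20809. Detection calls were not used here.

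With 1 sample per group there is no estimate of replicate error, so no p-value was computed. The following choices were made before the data were examined: the floor of 6, the sizes of 1.5-fold and 2-fold, the 31 gene lists, the rule for named genes and most alternatives. A list was described by the median difference of its members past the floor (at least 5 needed), with a 95% bootstrap interval over members from 10000 draws, and by the percentile of its median among 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list stood apart under the 2.5th or over the 97.5th percentile, which describes these 2 samples and is not a test across cultures. The lists covered Polycomb complexes and their targets, the cell cycle, autophagy and lysosomes, FOXO and p53 targets, blood lineages and fibroblasts, ribosomes, mitochondria, stress responses, metabolism, BCR-ABL outputs and immediate early genes. The genes named were BMI1, the 12 with the largest positive and the 12 with the largest negative difference among named genes, PRC1 members that differed by at least 1.2-fold, up to 4 members of each other list with the largest absolute difference, and CCNG2 and CDKN2A in any case. Unnamed transcripts, small nucleolar, micro and Y RNAs and immunoglobulin or T cell receptor segments were counted but not named. Besides BMI1 the rule took 130 genes, of which 6 had a further probe set, and in 4 of these 6 it had the same sign.

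The spread of differences at a given level was described by the robust SD (1.4826 times the median absolute deviation) in bins of mean expression, which was 0.25 for means up to 6.15 and 0.10 for means from 10.9. Between probe sets of 1 gene, the pooled SD of the difference was 0.15 over 485 genes. The steps were tested on simulated data, 5 simulations of the 13471 genes with 200 changed by 2-fold. At the 1.5-fold size, 99.1% of the changed genes were called. On average 16.2 genes per simulation outside these 200 were called too, members of the shifted lists included. A list shift of 0.2 was called in 15 of 15 simulated lists, and 4 of 135 unshifted lists were called. Simulated genes varied independently of each other, so these rates do not cover lists whose genes vary together. Smaller list shifts were not simulated. Alternatives were the mean or median over probe sets, centring on the sample median, subtraction of a loess trend (span 0.3), quantile normalization, no floor or floors of 5, 7 and 8, random lists unmatched or matched in 10 bins, and each list without its largest member. Removal of a trend with genomic span, matching of random lists on span in 5 by 5 bins and lists without shared members were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.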

Results

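Gene expression was measured in K562, a human chronic myeloid leukaemia line that carries the BCR-ABL fusion, makes embryonic and fetal globins and lacks functional p53. The cells held a doxycycline-inducible short hairpin RNA against BMI1, a subunit of Polycomb repressive complex 1 (PRC1), which is known for holding developmental genes and CDKN2A in a repressed state. One culture received doxycycline for 96 h and the other received none, so each group held 1 sample and 1 array. The labels give no incubation time for the control culture. Any other difference between the 2 cultures, in time or handling, would therefore coincide with the doxycycline difference. Both RNAs had an integrity number of 10, and 0.3 µg of each was labelled. The comparison asked how the transcriptome of these cells differed once the hairpin had been induced. The values were log2 RMA values of 33297 probe sets, with a median of 6.77 in the doxycycline sample and 6.78 in the control sample. Across probe sets, which are not independent replicates, the 2 samples correlated with Pearson's r of 0.994. Because there was no replicate, no difference below could be set against a spread between replicates, and no test of single genes was made. Differences are log2 values with doxycycline minus without, and the number of arrays limits their precision.

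The targeted transcript was lower in the doxycycline sample. The probe set annotated to both BMI1 and the COMMD3-BMI1 read-through (7926609) stood at 10.00 with doxycycline and 10.84 without it, a difference of -0.84, or 1.79-fold lower. By this measure 55.9% of the signal remained. None of the 13471 genes compared had a difference as low (0 of 13471). The robust SD of the differences among genes of similar level was 0.13. The probe set annotated to COMMD3 and the same read-through, which covers the neighbouring gene upstream, stood at 8.91 with doxycycline and 8.94 without, a difference of -0.03. The labels of the 2 samples therefore matched the direction of their BMI1 signal.

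More genes were higher than lower in the doxycycline sample, and several of the bright ones belonged to amino acid metabolism. Of the 13471 genes, 49 (0.364%) were at least 1.5-fold higher and 15 (0.111%) at least 1.5-fold lower. In the simulated data, on average 16.2 genes reached this size in either direction without a simulated 2-fold change. At 2-fold, 6 genes were higher and 0 lower. PHGDH, the first enzyme of serine synthesis, was 2.29-fold higher, at 10.48 with doxycycline and 9.28 without. SLC7A11, the cystine and glutamate exchanger, was 2.04-fold higher, at 9.47 against 8.43. TCN1, a cobalamin-binding protein, was 2.05-fold higher, and IL20RB, a cytokine receptor chain, 2.03-fold higher. ALDH1L2, a mitochondrial folate enzyme, was 1.95-fold higher, and RPS6KA5, a stress-activated kinase, 1.93-fold higher. WARS1, the cytosolic tryptophanyl-tRNA synthetase, was among the brightest genes that differed and was 1.71-fold higher, at 11.14 against 10.36. The other named genes at the top were SYTL3 at 1.08, KRTAP5-5 at 0.97, APOL6 at 0.87, IGLON5 at 0.87 and TM6SF1 at 0.80. SYTL3, KRTAP5-5 and APOL6 were under 6 without doxycycline and passed the floor only through the doxycycline sample. The remaining gene past 2-fold was a dim Y RNA.

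Among the 15 genes at least 1.5-fold lower, COX7B, a subunit of cytochrome c oxidase, was the brightest, at 9.21 with doxycycline and 9.82 without, or 1.53-fold lower. POU5F1B, a retrogene close in sequence to POU5F1, differed by -0.73, and the olfactory receptor gene OR14C36 by -0.76. The heat shock pseudogene HSP90AA6P differed by -0.66, and both it and POU5F1B share sequence with a parent gene, so their values are uncertain. CCDC88C (-0.61, but -0.25 at its other probe set), CFAP276 (-0.61), the long non-coding RNA UCA1 (-0.59) and the neurofilament gene NEFH (-0.59) followed. INTU (-0.58), TRIM63 (-0.58) and DHRS2 (-0.58) lay just under the 1.5-fold size. OR14C36, POU5F1B, CFAP276 and TRIM63 were under 6 with doxycycline and passed the floor only through the control sample. DUSP5P1 differed by -0.66 at its brighter probe set and by 0.18 at its dimmer one, so its direction was not settled. Dim genes were over-represented on both sides: 55.1% of the higher and 53.3% of the lower genes had a mean under 7, against 24.7% of all genes compared. The counts followed the floor on dim genes, with 77 higher and 66 lower when no floor was set and 16 higher and 4 lower with a floor of 8.

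**Figure D1:**
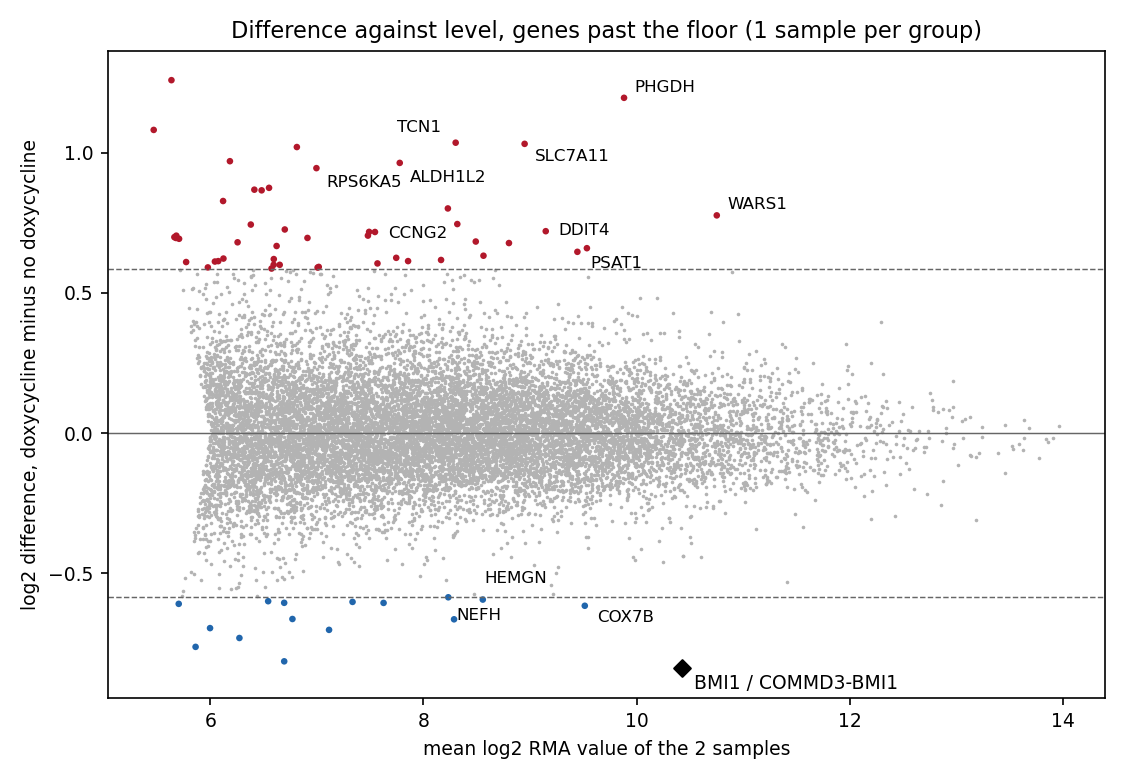
Each point is 1 of 13471 genes, with the mean log2 RMA value of the 2 samples on the horizontal axis and the log2 difference, doxycycline minus no doxycycline, on the vertical axis. Dashed lines mark 1.5-fold, red points are the 49 higher and blue points the 15 lower genes, and the black diamond is the BMI1 probe set at -0.84. Differences of dim genes spread more widely, with a robust SD of 0.25 in the dimmest and 0.10 in the brightest of 20 bins.

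Gene groups were compared through 31 fixed lists, each described by the median difference of its members and by that median's percentile among 10000 random lists of equal size matched on expression. Of the 30 lists with enough members, 4 lay above and 5 below the range that held the middle 95% of random lists, where 1.5 lists would be expected outside this range if genes were independent and nothing differed. The ATF4 and amino acid response list was the highest. Of its 31 members past the floor, 30 were higher with doxycycline and 5 were at least 1.5-fold higher, namely PHGDH, SLC7A11, WARS1, DDIT4 (an inhibitor of mTORC1, 0.72) and PSAT1 (the second step of serine synthesis, 0.65). The member that was not higher was CEBPB at -0.04. The median was 0.24, a 1.18-fold difference, with a 95% bootstrap interval over members from 0.20 to 0.32, at the 100th percentile. DDIT3 differed by 0.57, ATF4 itself by 0.23 and ASNS, the asparagine synthetase gene, by 0.48. PSAT1, DDIT3, ATF4, ASNS and CEBPB were chosen for mention after their values were seen. Bootstrap intervals here and below cover the spread between members only, not the error of the samples.

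The p53 target list also lay high, with 16 of 19 members higher and a median of 0.17 (0.09 to 0.27) at the 100th percentile, although K562 cells lack functional p53 and 0 members reached 1.5-fold. Its largest differences were TNFRSF10B, a death receptor gene, at 0.41, TP53INP1 at 0.38, GDF15 at 0.35 and DDB2 at 0.35. With the members shared with other lists left out, an alternative chosen after the values were seen, the median of the remaining 12 was 0.17 (-0.01 to 0.26) at percentile 99.9, with 9 of 12 higher. Cell cycle inhibitors had a median of 0.10 (-0.01 to 0.23) at percentile 98.4, with 8 of 13 members higher. CCNG2, a cyclin that opposes cell cycle progression, was 1.64-fold higher, at 7.85 with doxycycline and 7.13 without. CDKN1A differed by 0.28, CDKN1B by 0.23 and BTG1 by 0.23. CDKN2A, the classical target of BMI1 repression, was near the floor at 6.67 with doxycycline and 6.72 without. Detection calls were not used, and whether this line retains the CDKN2A gene was not examined. Whether CDKN2A was expressed in either sample is therefore not shown, and its value cannot tell whether repression was lifted. FOXO targets had a median of 0.08 (-0.04 to 0.22) at percentile 98.5, with 17 of 25 members higher, led by DDIT4, CCNG2, KLF6 (0.36) and BCL6 (0.36). The last 2 lists share CCNG2, CDKN1B and RBL2, and neither kept its place once members shared with other lists were left out. The medians were then -0.0103 at percentile 40.9 for cell cycle inhibitors and 0.04 at percentile 76.6 for FOXO targets, and without CCNG2 alone the first list had a median of 0.06 at percentile 88.2.

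The lists of ribosome biogenesis and MYC targets, of mitochondrial ribosomal proteins and of the nuclear respiratory chain were lower in the doxycycline sample, by small amounts that most members shared. In the ribosome biogenesis and MYC target list, 20 of 22 members were lower, with a median of -0.15 (-0.18 to -0.07) at percentile 0. Its largest differences were SRM at -0.26, RRP12 at -0.24, ODC1 at -0.22 and NOP16 at -0.21. Of 63 genes for mitochondrial ribosomal proteins, 58 were lower, with a median of -0.11 (-0.15 to -0.08) at percentile 0. MRPS12 differed by -0.47, MRPS17 by -0.44, MRPL41 by -0.33 and MRPL1 by -0.31. Nuclear genes of the respiratory chain had a median of -0.12 (-0.15 to -0.06) at percentile 0, with 45 of 55 members lower, among them COX7B at -0.62, NDUFB3 at -0.44, NDUFA2 at -0.35 and ATP5MC3 at -0.30. Genes for cytosolic ribosomal proteins stood closer to 0, with 37 of 57 lower and a median of -0.03 (-0.05 to -0.02) at percentile 7.73. Mitochondrially encoded genes were not analysed here (0 measured).

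Erythroid markers were lower as a list, with 16 of 25 members lower and a median of -0.09 (-0.18 to 0.05) at percentile 0.31. HEMGN, an erythroid nuclear protein gene, differed by -0.57, HBB by -0.47 close to the floor (5.95 against 6.42), HBZ, the embryonic zeta globin gene, by -0.44, and HBE1, the embryonic epsilon globin gene, by -0.31. A further HBZ probe set differed by -0.65. The near-identical pairs HBA1 and HBA2 and HBG1 and HBG2 were not analysed here. Haem synthesis genes in the list, named after their values were seen, went both ways. ALAS2 (0.22), ALAD (0.20), PPOX (0.11) and UROS (0.03) were higher, and CPOX (-0.14), UROD (-0.14) and FECH (-0.09) were lower. PRC1 subunits other than BMI1 had a median of -0.09 (-0.11 to 0.12) at percentile 0.93, with 12 of 18 members lower. The mean of that list was -0.02, and no member differed by 1.2-fold.

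**Figure D2:**
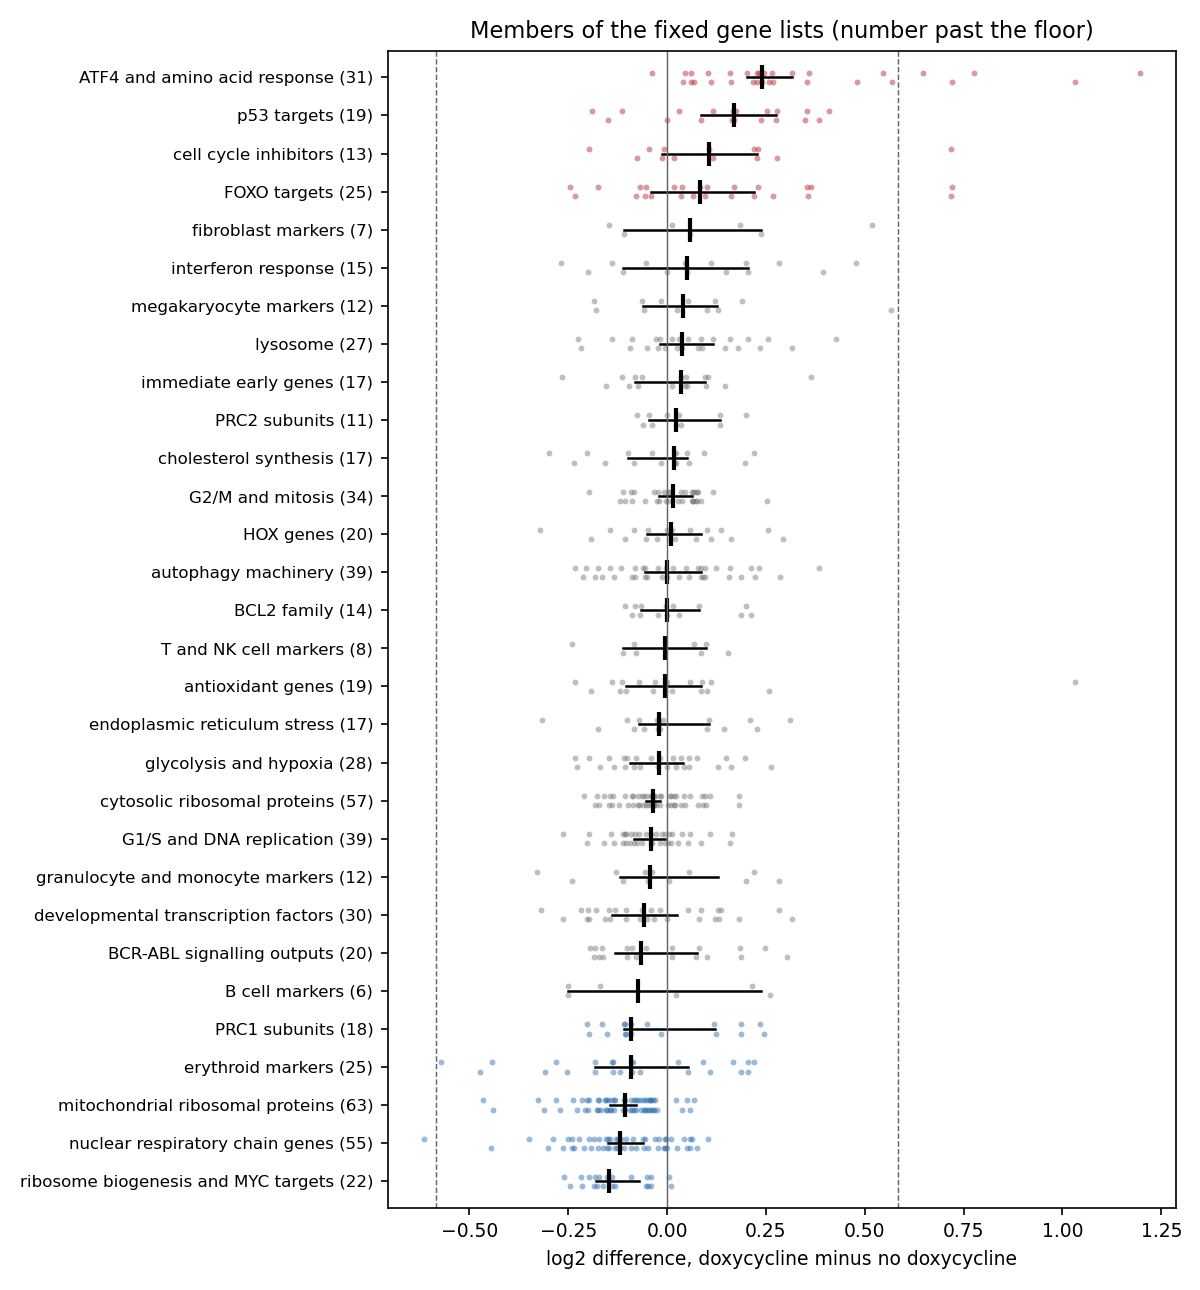
Rows are the 30 gene lists with enough members, ordered by median, and points are the members' log2 differences, doxycycline minus no doxycycline. Black ticks are medians, black lines their 95% bootstrap intervals over members, and dashed lines mark 1.5-fold. Red marks the 4 lists above the middle 95% of matched random lists, with the ATF4 and amino acid response at the top (0.24), and blue the 5 lists below it, with ribosome biogenesis and MYC targets at the bottom (-0.15).

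The other 21 lists stayed within the middle 95% of random lists. Classical Polycomb targets were among them. HOX genes had a median of 0.01 over 20 members (percentile 60.1), with HOXD13 at -0.32, HOXD4 at 0.29 and HOXB6 at 0.26. Developmental transcription factors had a median of -0.06 over 30 members (percentile 6.52), with SOX17 at -0.32, PAX6 at 0.32 and EVX1 at 0.28, and lay at percentile 2.44 with a floor of 7. With a floor of 8, the HOX and developmental lists kept too few members, so both medians describe mostly dim genes. Whether those genes were expressed at all was not tested. PRC2 subunits had a median of 0.02 over 11 members (percentile 70.4), and JARID2 at 0.20 and AEBP2 at 0.13 were the furthest from 0. For growth and survival, genes of G1/S and DNA replication had a median of -0.04 (percentile 4.63) with 27 of 39 lower, led by GINS2 at -0.26, MCM2 at -0.20 and UHRF1 at -0.20. After quantile normalization of the 2 columns this list lay at percentile 2.21. G2/M and mitosis genes had a median of 0.02 (percentile 78.9), with CDC25C at 0.25 and CKS2 at -0.20. The BCL2 family had a median of -0.00046 (percentile 45.8), with MCL1 at 0.21 and PMAIP1 at 0.20. Genes downstream of BCR-ABL signalling had a median of -0.07 (percentile 3.41), with PHLDA1 at 0.30, SOCS2 at 0.25 and SOCS3 at -0.19, and moved to percentile 1.06 without a floor and to a median of 0.01 with a floor of 8.

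Autophagy genes split evenly, with 20 of 39 members higher, 19 lower and a median of 0.000387 (percentile 44.8). TP53INP1 differed by 0.38, NBR1 by 0.29, TAX1BP1 by 0.23 and BNIP3 by -0.23. Lysosomal genes had a median of 0.04 (percentile 86.5), with LAMP2 at 0.43 and ASAH1 at 0.32, and stood just above the range of random lists with a floor of 8. Genes of endoplasmic reticulum stress had a median of -0.02 (percentile 31.6), with SDF2L1 at -0.32, EDEM1 at 0.31 and HERPUD1 at 0.23. The interferon response list, which a hairpin RNA can trigger, had a median of 0.05 (percentile 81.0), with IFIT3 at 0.48 and IFI6 at 0.40. Antioxidant genes had a median of -0.00617 (percentile 47.5), with SLC7A11 at 1.03, HMOX1 at 0.26 and SOD2 at -0.23. Glycolysis and hypoxia genes had a median of -0.02 (percentile 27.3), with VEGFA at 0.26. Cholesterol synthesis genes had a median of 0.02 (percentile 67.4), with EBP at -0.30 and MVK at -0.24. Immediate early genes had a median of 0.04 (percentile 77.4), with KLF6 at 0.36 and ZFP36 at -0.26. The mean had the opposite sign to the median in the endoplasmic reticulum stress (0.01), BCL2 family (0.02), antioxidant (0.04) and cholesterol (-0.02) lists.

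Markers of other blood lineages and of fibroblasts did not stand apart at the floor of 6. Megakaryocyte markers had a median of 0.04 over 12 members (percentile 75.3), and FLI1, a megakaryocytic transcription factor gene, differed by 0.57, at 6.68 with doxycycline and 6.11 without. Granulocyte and monocyte markers had a median of -0.04 (percentile 20.7), with ELANE at -0.33 and LYZ at 0.28. The median was -0.00475 for T and NK cell markers (percentile 44.3), with ZAP70 at -0.24, and -0.07 for B cell markers (percentile 20.9), with BLK at 0.26. Fibroblast markers had a median of 0.06 (percentile 75.3), with COL6A3 at 0.52 and FN1 at 0.24. B cell markers lay at percentile 2.19 with a floor of 5, and fibroblast markers at percentile 98.3 with no floor.

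**Figure D3:**
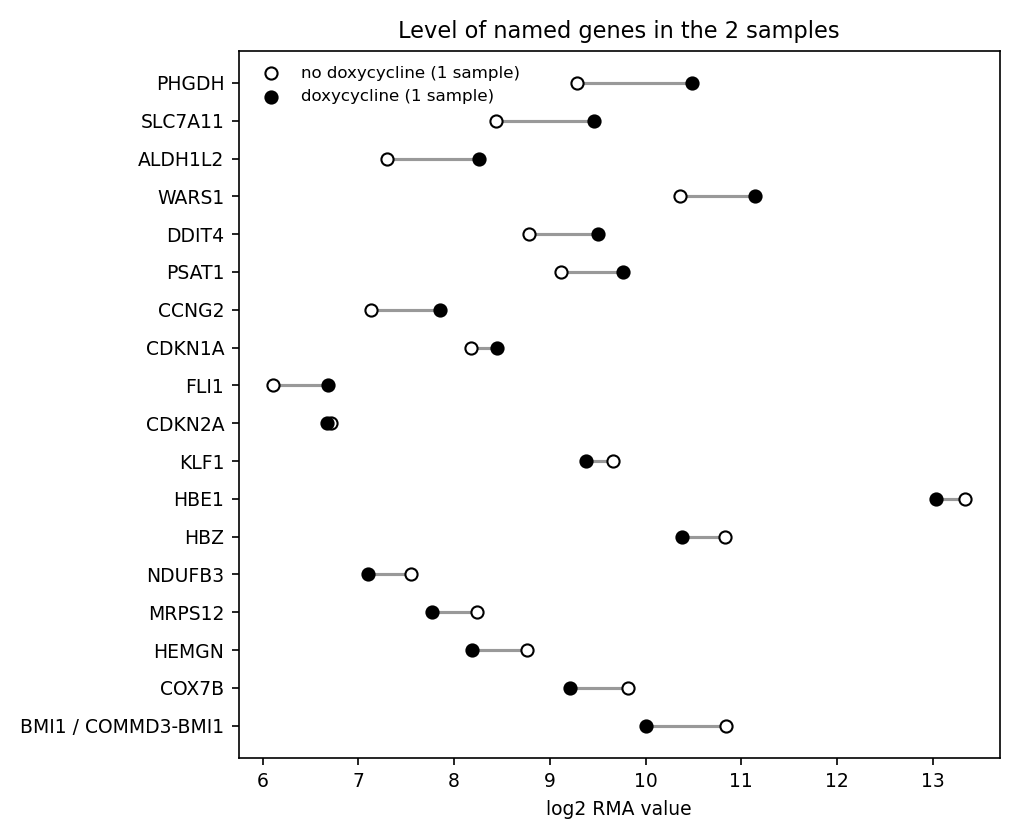
Log2 RMA values of named genes in the control sample (open circles) and the doxycycline sample (filled circles), 1 sample each, so no error bar can be drawn. PHGDH, SLC7A11, ALDH1L2, WARS1, DDIT4, PSAT1 and CCNG2 lie to the right with doxycycline. CDKN2A, near the floor, hardly differs (6.67 against 6.72). The globin genes, COX7B and the BMI1 probe set lie to the left.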

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

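The tests on endoplasmic reticulum stress, on doxycycline alone, on short abundant transcripts and on admixture were chosen only after the result was seen. Those on gene length were also added after the data had been seen, with their criteria set before their own outcome.

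Signal that differed between the samples also lay outside the gene comparison. Of 5756 probe sets with no symbol here that passed the floor, 39 were at least 2-fold higher and 55 at least 2-fold lower with doxycycline, against 6 and 0 of the 13471 genes. The extremes were -3.81 (probe set 7894869) and 2.07 (probe set 7893615). Of the 39 and 55 together, 88 carry numbers below every named one, and differences there were wider, with a robust SD of 0.23 against 0.20 for other unnamed probe sets and 0.15 for genes. What these probe sets measure is not given in the sources used here, and control probe sets among them are not excluded. Of 1191 probe sets with several symbols, 6 were at least 1.5-fold higher and 1, the BMI1 probe set, at least 1.5-fold lower.

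The first pattern weighed was the higher level of amino acid response genes. A trend with gene length existed across genes (Spearman's rho 0.18, genes not being independent replicates), but against random lists matched on genomic span as well the list stayed at the 100th percentile. Endoplasmic reticulum stress, which also acts through ATF4, was argued against by its own list, at percentile 31.6. Doxycycline acting without the hairpin stays open, because 0 samples received doxycycline without the hairpin, and so does silencing of BMI1, which cannot be told apart from it in this design. Other differences between the 2 cultures, such as time in culture, stay open too, since each group held 1 sample. Whether the response followed amino acid supply or mitochondrial stress was not tested.

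The second pattern was the lower level of the mitochondrial ribosomal and respiratory chain lists. Gene length was argued against in the same way, since both the mitochondrial ribosomal and the respiratory chain lists stayed at percentile 0 (0 and 0) with random lists matched on span. If all short and abundant transcripts had lost share, cytosolic ribosomal protein genes should have been as low. Against their median, mitochondrial ribosomal genes differed by -0.07 (-0.11 to -0.04) and respiratory chain genes by -0.08 (-0.12 to -0.025). The cytosolic ribosomal protein genes were mostly brighter than the members of both lists, so this comparison was not made at equal level. Transcript length itself, as opposed to genomic span, was not matched. Doxycycline acting without the hairpin, which as an antibiotic is known to inhibit mitochondrial translation, could account for this pattern. With 0 samples given doxycycline without the hairpin, it cannot be told apart from silencing of BMI1, nor from other differences between the 2 cultures.

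The third pattern was the lower level of erythroid genes as a list. Against gene length as its whole cause, the list lay at percentile 0.905 with random lists matched on genomic span as well, compared with 0.31 on expression alone. Admixture of other cells would dilute all transcripts made by K562 cells alone, and of 25 members 0 were higher and 5 lower by more than 2 local robust SDs, which leaves admixture of other cells open. At the floor of 6, 0 of 4 marker lists of other cells stood apart high (megakaryocyte markers, which K562 cells can make themselves, not counted), but fibroblast markers lay at percentile 98.3 with no floor, so these lists do not settle it. BMI1 silencing, doxycycline and other differences between the 2 cultures were not tested as sources of this pattern and stay open too.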

How the results depend on the processing

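Matching on genomic span, removal of the span trend and lists without shared members were tried only after the data were seen. The BMI1 difference was -0.83 under centring, loess and quantile normalization. Averaging over probe sets was not run for it, because it has 1. Genes at least 1.5-fold higher numbered 77 with no floor, 26 with a floor of 7 and 16 with a floor of 8, and genes at least 1.5-fold lower numbered 66 with no floor, 32 with a floor of 5, 9 with a floor of 7 and 4 with a floor of 8. At 2-fold, 3 were higher with a floor of 8, and 4 were lower with no floor and 2 with a floor of 5. A higher floor admits fewer genes, and dim genes spread more widely. The scaling and probe set alternatives, with the span trend included, gave 44 to 56 higher and 13 to 16 lower genes at 1.5-fold.

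Lists that stood apart high numbered 2 without each list's largest member, where FOXO targets reached 97.2 and cell cycle inhibitors 88.2. FOXO targets also stayed within the bounds at floors of 5 (97.2) and 7 (97.475), and cell cycle inhibitors with the span trend removed (91.6). The median of cell cycle inhibitors turned to -0.0103 with shared members left out, inside its bootstrap interval. Amino acid response genes (0.24 to 0.26), p53 targets (0.16 to 0.18) and the 5 lower lists stood apart under 14 of 14 settings. Besides that value, over all lists and alternatives 321 medians stayed in their bootstrap interval and 1 left it, that of cytosolic ribosomal proteins with the span trend removed (-0.02). Of the named genes' values 644 stayed within the probe set SD and 6 moved, those of CCDC88C, DUSP5P1 and RPS15 by the mean or median over probe sets. A floor of 8 left too few members in the HOX, developmental, interferon and 4 other lineage lists, and a floor of 7 in those of T and NK cells, B cells and fibroblasts. No paired analysis was possible because each group holds 1 sample. Signal limits dim genes most, at a robust SD of 0.25 against 0.10 for the brightest.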

Other observations

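The lists in this part were chosen after the gene values had been seen. No value in it separates BMI1 silencing from doxycycline or from other differences between the 2 cultures.

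Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, had a median of 0.11 (0.02 to 0.23) over 19 genes at the 100th percentile, with 14 higher, among them WARS1 at 0.78, AARS1 at 0.32, MARS1 at 0.27 and CARS1 at 0.27. Their mitochondrial counterparts had a median of -0.02 over 16 genes at percentile 30.1, with 9 lower. Of 15 genes of serine synthesis and folate one-carbon metabolism, 13 were higher, led by PHGDH, ALDH1L2, PSAT1, SLC1A4 (0.55) and MTHFD2L (0.35), but the median of 0.08 reached only percentile 95.9. Amino acid transporters had a median of 0.09 over 12 genes at percentile 98.2, or the 95.9th when random lists were matched on genomic span. Several of these genes are also in the amino acid response list, so the lists are not independent of it, and they were not run without the shared members.

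Zinc finger genes with ZNF symbols formed the broadest higher group, with 232 of 361 higher and a median of 0.06 at the 100th percentile, also with random lists matched on genomic span. ZNF45 and ZNF443 both differed by 0.61. The signal annotated to small nucleolar RNAs went the other way, with 82 of 107 lower and a median of -0.11 at percentile 0. Whether it came from the mature small RNAs was not tested. Proteasome subunits had a median of -0.06 over 28 genes, with 25 lower, at percentile 1.46, or 4.25 with span matching. Genes of the tricarboxylic acid cycle stood at 0.01 over 14 genes (percentile 67) and HLA class I and antigen processing genes at 0.09 over 9 genes (percentile 94.0). Bright genes at least 1.5-fold higher outside these groups included, besides TCN1 and TM6SF1, several named after their values were seen, CD44 at 0.66, a cell surface receptor gene, ALDH1A1 at 0.68, RAB27B at 0.68, SEL1L3 at 0.75, NIBAN1 at 0.63 and ARID5B at 0.62.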
